A study of Mus musculus with 2 samples.

How the data were processed

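Single-cell RNA sequencing was done on the esophageal epithelium of mouse embryos at E18.5 (days of embryonic development), with 1 library labelled wild type and 1 labelled p63-KO. Per the labels' protocols, the muscle layer was pulled off, the tissue was kept in dispase for 5 min, and the epithelial layer was then taken apart at 37 °C with trypsin (0.1%, 10 min) and passed through a strainer of 40 µm. The labels give the wild-type library the genotype p63-CreER, a carrier of the targeted allele, and the p63-KO library 2 copies of that allele. Per the submitters' processing notes, Cell Ranger 7.1.0 and the mouse build mm10 were used. Per the labels' protocols a droplet kit that counts the 3' ends of transcripts was used. The annotation release, the cell calling and the counting of intronic reads are not given in the sources used here. The deposited values are counts, whole-number UMI (unique molecular identifier) counts per gene and barcode for 32285 genes, and nothing shows that they were normalized by the authors.

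The wild-type library held 6034 barcodes with 76472445 UMIs, and the p63-KO library 2821 barcodes with 86504624 UMIs. Barcodes with at least 500 genes, at least 1000 UMIs and at most 10% mitochondrial UMIs were kept, which left 5787 and 2422. Doublets were scored within each library as the share of simulated doublets among a cell's neighbours. The highest scores were removed at a rate of 0.8% per 1000 cells, 268 wild-type and 47 p63-KO cells, leaving 5519 and 2375. On simulated data, 35% of 100 planted random doublets were called in the wild-type library and 25% in the p63-KO library, so part of the doublets remained.

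The kept cells of both libraries were log-normalized and clustered jointly, without integration, on 2000 variable genes, 30 principal components, 20 neighbours and Leiden resolution 1 (leidenalg 0.10.2, igraph 0.11.9, scikit-learn 1.9.0, numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3 in Python 3.11.15). Mitochondrial, ribosomal protein, haemoglobin, Gm-numbered and sex-linked genes were kept out of the variable genes. A cluster was named after the cell type whose fixed markers had the highest mean detection, if at least 3 of them were found in at least 25% of its cells. A cluster of low depth with none of its markers among its leading genes stayed unnamed. The epithelial-like cells of each library were then clustered apart at resolution 0.6, and a subcluster was named if at least 3 markers of a type were found in at least 25% of its cells and were at least 2-fold higher than in the other cells. The markers were fixed in advance, but these thresholds for naming were not.

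UMI counts were summed over the epithelial-like cells of each library and scaled to CPM (counts per 1e6 UMIs). The log2 ratio of a gene was taken between p63-KO and wild-type CPM, each with 1 added, so that ratios of weakly expressed genes are understated, while folds were taken from the CPM without that addition. A gene was measured if it had at least 5 CPM in either library, which held for 11774 genes. With 1 library per group there was no test between groups and no replicate check. Intervals are exact 95% Poisson intervals for CPM, exact conditional binomial intervals for folds and exact binomial (Clopper-Pearson) intervals for shares of cells, and cover counting error only. A fold against a count of 0 was taken against 3 counts over the summed cells, and a share of 0 is given with the limit that 3 counts allow or with the exact upper limit. Each gene list is described by the median log2 ratio of its measured members, by the number of members at least 2-fold higher or lower, and by the percentile of the median among 10000 random lists of the same size matched on mean expression. The random lists do not match genes that are expressed together, so this percentile describes a list and is not a test. To compare shares of cells, each cell was thinned to 2000 UMIs, which left out 82 wild-type and 24 p63-KO epithelial-like cells.

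The 26 gene lists, the markers, the cell filter, the clustering resolutions, the pseudocount, the floor and the rule for named genes were fixed before the data were examined. The lists held 493 different genes, of which 0 stood in more than 1 list and 70 were also cell type markers. Named were Trp63, and the 12 genes with the highest and the 12 with the lowest log2 ratio among genes with at least 100 CPM in the library where they were higher, a UMI in at least 10% of its epithelial-like cells, and more CPM there than in its other cells. Mitochondrial, ribosomal protein, haemoglobin, Xist, Tsix, Y-linked, Gm-numbered and Rik genes were left out. From each list the rule took up to 4 members with the largest absolute ratio, up to 2 that went the other way by at least 2-fold, and any with at least 500 CPM. Values of some genes the rule takes are not reported here. Other genes are named in the text as chosen after their values were seen. Coordinates are those of GENCODE M21 on the same build, in which 32158 of the 32285 gene identifiers were found.

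The ratios were tested on simulated data with 200 of 10667 genes changed. Without the added 1 CPM the median ratio of 50 genes planted at a log2 ratio of -2 came out at -2.00, and with it at -1.88. The 95% interval held the true value for 95.1% of the 10467 unchanged genes. Of 100 random lists, 94% fell between the percentiles 2.5 and 97.5. Alternatives covered the cell filter, doublets, clustering, scaling, pseudocount, floor and cell subsets. The comparison of fibroblast-like cells and the spread of ratios by compartment were not made, since the wild-type library held 10 such cells, under the minimum of 100.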

Results

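The data compare the epithelium of the mouse esophagus between a library labelled p63-KO and a library labelled wild type. Trp63 encodes p63, a transcription factor of stratified epithelia and their basal cells. The esophageal epithelium of embryos at E18.5 was taken from p63-KO embryos and littermate controls and profiled cell by cell, with 1 library per group. Per the labels, the controls, called wild type here, carried the targeted allele (p63-CreER), and the p63-KO embryos had 2 copies of it. Each library held cells with Xist RNA and cells with Y-linked RNA, so each pooled at least 2 embryos. After filtering, 5519 wild-type cells with a median of 10927 UMIs and 2375 p63-KO cells with a median of 19307 UMIs remained. There were no replicates in either group, so every difference below is one between these 2 libraries, and its interval covers counting error only.

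The wild-type library was almost wholly epithelial, while the p63-KO library also held connective tissue and vessel cells. Epithelial-like cells made up 5362 of 5519 wild-type cells, 97.2% (96.7 to 97.6), and 1679 of 2375 p63-KO cells, 70.7% (68.8 to 72.5). Fibroblast-like cells, led by Mfap4, Col1a1 and Col3a1, were 10 cells (0.181%) in the wild-type and 515 cells (21.7%) in the p63-KO library. The p63-KO library also held 69 endothelial-like cells, 74 smooth muscle or pericyte-like cells and 18 immune-like cells, against 1, 1 and 0 in the wild type. A cluster of low depth stayed unnamed, with 145 wild-type and 20 p63-KO cells. The layers were separated by hand, and this step can set these shares. The epithelial-like cells of the libraries fell into different joint clusters. Of 16 such clusters, 1 (the ciliated-like cluster 17) held at least 5 cells of each library, wild-type cells lay mostly in clusters 1, 3, 4 and 6 to 12, and p63-KO cells in clusters 2, 13, 14, 15 and 18.

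Trp63 RNA was lower in p63-KO epithelial-like cells but was still counted there. Trp63 (ENSMUSG00000022510, chromosome 16, 25683763 to 25892102, mm10) had 303 CPM (299 to 307) in the wild type and 118 CPM (116 to 121) in p63-KO, 2.57-fold lower. The log2 ratio was -1.35 (-1.40 to -1.32), and -1.77 when every cell weighed equally. A Trp63 UMI was found in 84.3% of wild-type and 67.0% of p63-KO epithelial-like cells. After thinning to 2000 UMIs the shares were 44.0% (42.7 to 45.4) and 17.1% (15.3 to 19.0). In p63-KO fibroblast-like cells, which should lack the gene, the shares were 1.94% at full depth and 0 of 509 cells after thinning. The kit counts 3' ends, and the labels do not say which part of the gene the allele interrupts, so these counts do not check the genotype. The wild-type library also carried the allele, and how much of its Trp63 RNA came from that allele is not known.

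**Figure D1:**
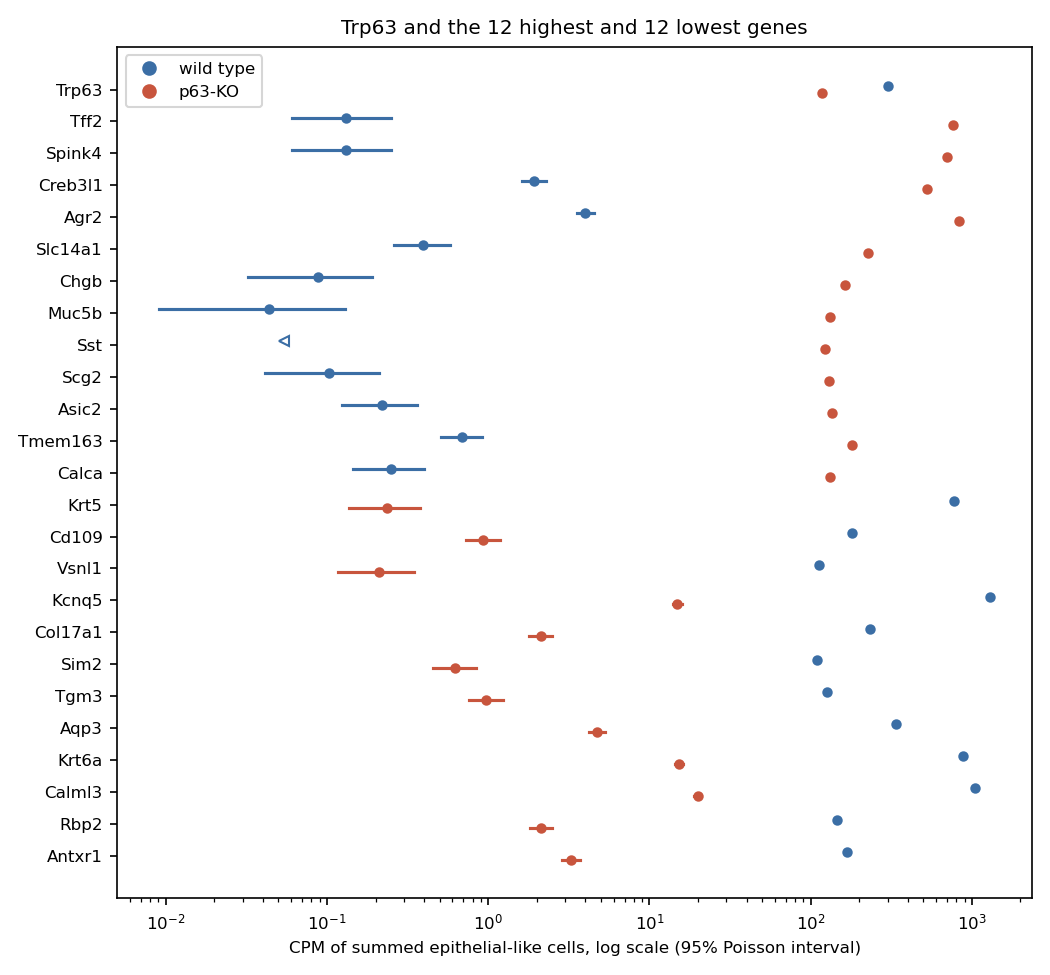
CPM of Trp63 and of the 12 highest and 12 lowest genes by ratio (rows) among those that met the naming rule, on a log scale. Values are from the summed epithelial-like cells of the wild-type (blue) and p63-KO (red) library. Krt14 and Krt17 did not meet the rule. Bars are 95% Poisson intervals and the open triangle is the exact upper limit for Sst, which had 0 wild-type UMIs. Krt5 stands at 769 CPM in the wild type and 0.237 CPM in p63-KO, and Tff2 at 0.132 and 764 CPM.

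Basal cell keratins were nearly missing from p63-KO epithelium. Krt5 (chromosome 15, 101707070 to 101712898), the keratin of basal cells in stratified epithelia, had 769 CPM (762 to 775) in the wild type and 0.237 CPM (0.138 to 0.379) in p63-KO. Its partner Krt14 had 301 and 0.933 CPM, and Krt17 283 and 5.47 CPM. Krt15 remained abundant, with 10549 and 4878 CPM, 2.16-fold lower in p63-KO. Of 19 measured genes of the list of basal cell keratins and receptors, 15 were at least 2-fold lower and 1 at least 2-fold higher. The water and glycerol channel Aqp3 was 71.9-fold lower and the growth factor receptor Fgfr2 2.66-fold lower, while the hyaluronan receptor Cd44 was 4.75-fold higher. The median log2 ratio was -1.81, below those of all 10000 random lists. Since random lists do not match genes that are expressed together, such a rank, here and below, only describes the list.

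The squamous program was lower as a group. Of 26 measured squamous differentiation genes, 23 were at least 2-fold lower in p63-KO and 0 at least 2-fold higher, with a median log2 ratio of -2.60, below those of all 10000 random lists. The transglutaminase Tgm3, which cross-links the cell envelope, was 129.7-fold lower, Krt6a 57.5-fold, the calmodulin-like Calml3 52.6-fold and cornifelin (Cnfn) 75.5-fold. Krt13 and Krt4, the keratins of suprabasal esophageal cells, were lower but abundant, with 2507 and 1416 CPM in p63-KO against 6949 and 4672 CPM in the wild type. Sfn was 6.91-fold and Ly6d 6.22-fold lower.

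RNA of many hemidesmosome, basement membrane and desmosome genes was lower in p63-KO. Of 21 hemidesmosome and basement membrane genes, 10 were at least 2-fold lower and 1 higher, with a median log2 ratio of -0.87. Col17a1, the hemidesmosome collagen (chromosome 19, 47646344 to 47692094), had 233 CPM in the wild type and 2.12 CPM in p63-KO, 110.0-fold lower (93.8 to 129.9). Col7a1, which forms anchoring fibrils, was 57.9-fold lower, Col4a6 12.9-fold and Frem2 5.29-fold. The integrin Itga6 was 2.54-fold higher. Of 10 desmosome genes 8 were at least 2-fold lower, with a median log2 ratio of -1.29. Dsg3 was 21.4-fold, Dsc2 10.6-fold, Pkp1 6.70-fold and Dsp 2.45-fold lower, Perp had 1145 and 176 CPM, whereas Pkp2, a plakophilin of simple epithelia, was 9.10-fold higher. Both medians lay below those of all 10000 random lists.

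The rest of the 12 genes with the lowest ratios among genes that met the naming rule had varied functions. Krt14 and Krt17, with log2 ratios of -7.29 and -5.46, did not meet it. They had more CPM in the other wild-type cells, 465 and 526 CPM, than in the epithelial-like ones. The GPI-anchored protein Cd109 was 193-fold lower (152 to 250), the calcium sensor Vsnl1 536-fold (325 to 958), the potassium channel Kcnq5 86.7-fold, the transcription factor Sim2 174-fold, the retinol-binding protein Rbp2 67.9-fold and Antxr1 51.6-fold.

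Genes of mucous and secretory cells were higher in p63-KO. Of 16 measured genes of this list 15 were at least 2-fold higher, with a median log2 ratio of 3.14, above those of all 10000 random lists. Agr2, a disulfide isomerase needed to make mucins, had 273 UMIs in the wild type and 826 CPM in p63-KO, 206-fold higher (183 to 233). The gel-forming mucin Muc5b (chromosome 7, 141839070 to 141873084) had 3 wild-type UMIs and 131 CPM in p63-KO, a ratio of 2979 with an interval of 1019 to 14450. Creb3l1, a transcription factor of secretory cells, was 272-fold higher, Muc1 121-fold, Muc16 31.5-fold, Wfdc2 6.28-fold and Galnt7 5.35-fold. Cyp2f2 stood at 1574 CPM in the wild type and 1422 CPM in p63-KO.

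The 2 highest genes by ratio among those that met the naming rule are known from mucous cells of the gut. Tff2, a trefoil peptide (chromosome 17, 31141049 to 31144282), had 0.132 CPM in the wild type and 764 CPM in p63-KO, and Spink4 had 0.132 and 701 CPM. The urea transporter Slc14a1 was 573-fold higher (394 to 870). Of 21 genes of the gastric and intestinal list only 3 were measured, with a median log2 ratio of 2.83, which ranged from 0.86 with the 50 most abundant genes left out of the total to 9.40 with members from 20 CPM on. Of these, Tff2 and the microvillus protein Vil1, 12.6-fold higher, were at least 2-fold higher, and 0 were at least 2-fold lower.

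Keratins of simple epithelia were higher or alike. Krt18 was 6.97-fold, Krt20 6.31-fold and Krt8 2.51-fold higher in p63-KO, and Krt7 1.84-fold. Krt19 had 964 and 1016 CPM. Of 6 genes 3 were at least 2-fold higher, and the median log2 ratio of 1.10 lay at percentile 99.7 of the random lists. Of 17 claudin and tight junction genes, 3 were at least 2-fold higher and 1 lower, with a median log2 ratio of 0.44 at percentile 98.8, which was 0.20 without the proliferating joint clusters. Cldn3 was 2.75-fold, Tjp3 2.38-fold and Cldn6 2.62-fold higher, and Cldn1 was 98.7-fold lower.

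**Figure D2:**
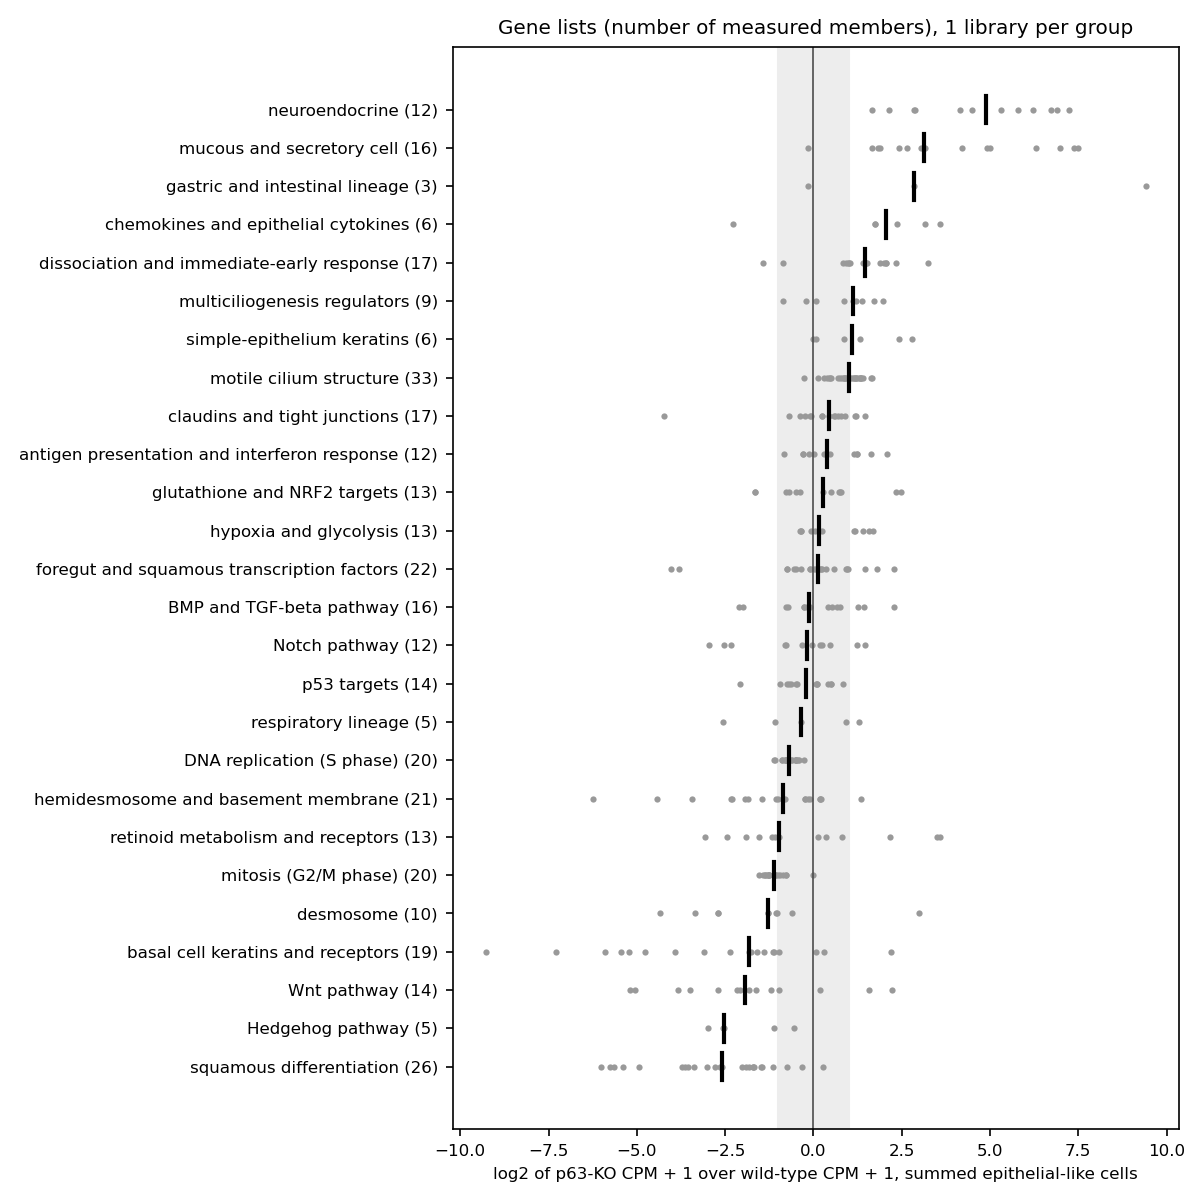
Log2 ratio of p63-KO over wild type (horizontal axis, each CPM with 1 added) of the measured members of each gene list (rows) in the summed epithelial-like cells. Grey points are genes, black bars the list medians and the shaded band marks less than a 2-fold difference. Medians run from -2.60 for squamous differentiation to 4.89 for the neuroendocrine list.

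Cilium genes were higher in p63-KO epithelium. Of 33 motile cilium genes 16 were at least 2-fold higher and 0 lower, with a median log2 ratio of 0.999, above those of all 10000 random lists. Weighing every cell equally gave 1.81. Pifo was 3.69-fold, Spag6l 3.75-fold, the dynein Dnah9 2.89-fold and Tppp3 2.58-fold higher. Of 9 regulators of multiciliogenesis 5 were at least 2-fold higher, with a median log2 ratio of 1.13 at percentile 95.7. Foxj1, the regulator of motile cilia, was 4.56-fold, Cdc20b 4.68-fold, Deup1 3.13-fold and Myb 2.60-fold higher. Foxj1 UMIs were found in 0.379% (0.232 to 0.584) of thinned wild-type and 2.96% (2.20 to 3.90) of thinned p63-KO epithelial-like cells, and in 1.08% and 14.9% without thinning. In p63-KO fibroblast-like cells, which should lack it, the shares were 0.196% (0.00497 to 1.09) and 0.388%. In the wild type Foxj1 had 399.7 CPM in the ciliated-like subcluster 9 and at most 1.32 CPM in the others, and in p63-KO 352 CPM in the ciliated-like subcluster 8 and 48.3 CPM in subcluster 6. At least 3 of 12 ciliated markers, a measure chosen after the data were seen, were found in 0.492% and 2.30% of thinned cells, and in 0.821% and 20.8% without thinning, against 0 of 509 thinned p63-KO fibroblast-like cells and 0.194% of them without thinning. The ciliated-like subcluster held 3.57% of p63-KO epithelial-like cells, so the unthinned share is not a share of ciliated cells. With the ciliated-like, neuroendocrine-like and Foxi1-rich clusters left out of both libraries, an alternative added after seeing the data, the median of the regulators was -0.28.

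Neuroendocrine genes were the list with the highest median in the main setting. With members from 20 CPM on, the gastric and intestinal list had a higher one, 9.40. All 12 measured genes were at least 2-fold higher in p63-KO, with a median log2 ratio of 4.89, above those of all 10000 random lists. The granule proteins Chgb and Scg2 were 1848-fold (849 to 5037) and 1264-fold higher (613 to 3145), and the calcitonin gene Calca 530-fold. Somatostatin (Sst, chromosome 16, 23889573 to 23890958) had 122 CPM in p63-KO and 0 UMIs in the wild type, at least 2265-fold higher by the exact interval and 2785-fold against 3 counts. The channel Asic2 was 619-fold and Tmem163 263-fold higher. At least 3 of 9 neuroendocrine markers, a measure also chosen after the data were seen, were found in 1 of 5280 thinned wild-type cells and in 274 of 1655 thinned p63-KO cells, 16.6% (14.8 to 18.4), against 0 of 509 p63-KO fibroblast-like cells, for which 3 counts allow a share of up to 0.589% and the exact interval one of up to 0.722% for cells with such UMIs at this depth. Without thinning they were found in 2 of 5362 wild-type cells and in 30.3% of p63-KO epithelial-like cells. The neuroendocrine-like subclusters held 20.8% of p63-KO epithelial-like cells, so the unthinned share is not a share of neuroendocrine cells. The neuroendocrine median was 3.09 with 5 CPM added, the lowest of 17 alternatives, and 6.10 at the highest.

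Regulators of foregut identity differed gene by gene. The list of 22 foregut and squamous transcription factors had a median log2 ratio of 0.13 at percentile 76.1, with 3 members at least 2-fold higher and 2 lower. Foxe1 was 18.1-fold lower and Tfap2a 199.6-fold lower, while Foxa2 was 3.67-fold, Meis1 2.76-fold and Isl1 18.7-fold higher. Of the 374 Isl1 UMIs in p63-KO, 334 came from the neuroendocrine-like subcluster 3, and without it Isl1 had 0.587 CPM (0.420 to 0.7996), against 0.278 CPM (0.168 to 0.435) in the wild type. Nfib had 419 and 815 CPM and Klf5 662 and 772 CPM. Sox2 UMIs were found in 34.1% of thinned wild-type and 26.0% of thinned p63-KO cells, and Pax9 UMIs in 34.9% and 24.7%. Without thinning these shares were 84.7% and 87.7% for Sox2 and 85.6% and 86.6% for Pax9. Nkx2-1, the lung and thyroid factor, was found in 1 of 5280 thinned wild-type cells and 0 of 1655 p63-KO cells, for which 3 counts allow a share of up to 0.181% and the exact interval one of up to 0.223% for cells with a UMI at this depth, not for cells that express the gene. Of 14 respiratory genes 5 were measured, with a median log2 ratio of -0.34 at percentile 16.1, which was 0.26 when the 50 most abundant genes were left out of the total and 0.23 when every cell weighed equally. Scgb3a2 was 15.1-fold and Foxp2 2.17-fold lower, Cbr2 was 2.44-fold higher, Foxp4 had 41.2 and 78.4 CPM, and Foxp1 1202 and 950 CPM.

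**Figure D3:**
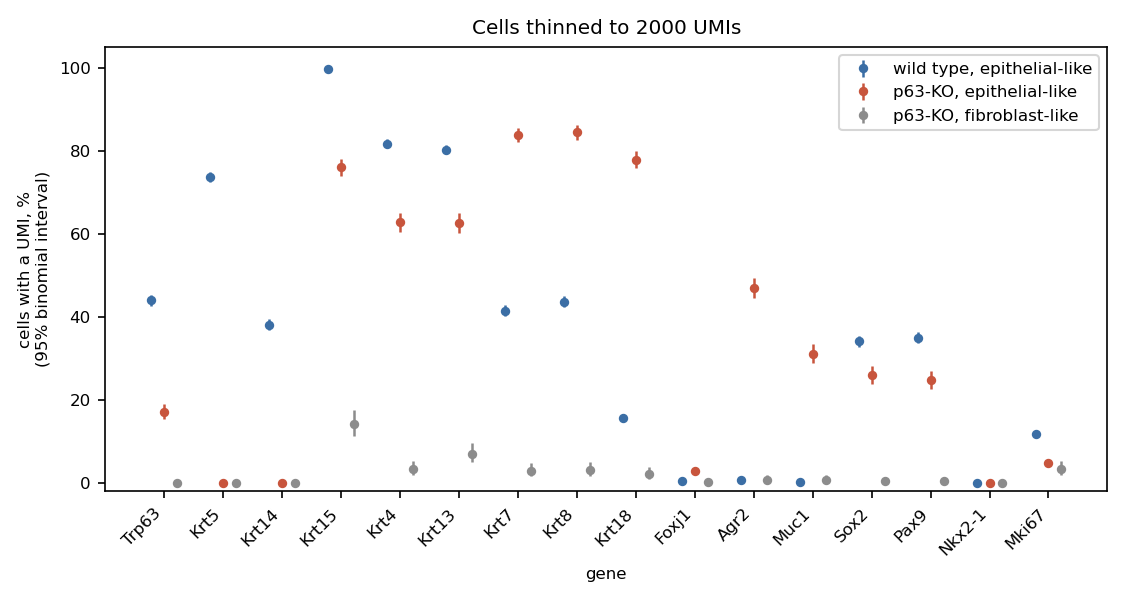
Share of cells with a UMI of each gene (horizontal axis) in percent (vertical axis) after thinning every cell to 2000 UMIs, with 95% binomial intervals, in epithelial-like cells of the wild-type (blue) and p63-KO (red) library and in p63-KO fibroblast-like cells (grey). Krt5 is found in 73.7% of wild-type and 0.0604% of p63-KO epithelial-like cells, and Agr2 in 0.682% and 47.0%.

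The thinned shares gave the same order as the CPM for the keratins. Krt18 was found in 15.6% of wild-type and 77.9% of p63-KO cells, Krt8 in 43.7% and 84.5%, and Krt7 in 41.5% and 83.9%. Krt15 was found in 99.8% and 76.0%, Krt13 in 80.3% and 62.7%, Krt4 in 81.7% and 62.8%, and Krt14 in 38.1% and 0.0604%. Muc1 was found in 0.322% and 31.2%. The p63-KO fibroblast-like cells held Krt15 in 14.1% of thinned cells and Krt13 in 7.07%, and Agr2 and Muc1 in 0.786%, genes that such cells should lack. Their median depth was 10809 UMIs before thinning. At full depth, with medians of 11061 UMIs in wild-type and 25207 in p63-KO epithelial-like cells, Krt14 was found in 67.0% and 1.43%, Agr2 in 3.21% and 76.1%, and Muc1 in 1.94% and 83.7%.

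Cell cycle genes were lower in p63-KO epithelium as summed. Of 20 mitosis genes 15 were at least 2-fold lower and 0 higher, with a median log2 ratio of -1.13. Hmmr was 3.10-fold, Bub1 2.95-fold, Aurkb 2.70-fold and Tpx2 2.68-fold lower. Of 20 DNA replication genes 2 were at least 2-fold lower, with a median log2 ratio of -0.70, and Uhrf1 was 2.21-fold and Rrm2 2.19-fold lower. Both medians lay below those of all 10000 random lists. At least 2 of 7 proliferation genes were found in 19.0% (18.0 to 20.1) of thinned wild-type and 8.64% (7.33 to 10.1) of thinned p63-KO cells, and in 33.9% and 37.1% without thinning. Mki67 was found in 11.9% and 4.71% after thinning. The p63-KO subcluster 2, led by cell cycle genes, held 17.0% of p63-KO epithelial-like cells, so the thinned share is not a share of cycling cells. Mki67 stood at 113 CPM in that subcluster, against 606 CPM in the wild-type subcluster 5, also led by cell cycle genes. In cells with Xist RNA alone the mitosis median was -0.83 and in cells with Y-linked RNA alone -2.04, both subsets added after seeing the data. Without the proliferating joint clusters it was 2.03 and the DNA replication median 0.12. This left 3964 of 5362 wild-type and 1677 of 1679 p63-KO cells, among the latter the subcluster of 285 cells led by cell cycle genes.

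Wnt and Hedgehog genes were mostly lower. Of 14 Wnt pathway genes 10 were at least 2-fold lower and 2 higher, with a median log2 ratio of -1.95, below those of all 10000 random lists. It was -1.25 with 5 CPM added and -1.09 with members from 1 CPM on. The receptor Lgr5 was 154-fold lower and the ligands Wnt10a, Wnt6, Wnt3a and Wnt4 were 51.7-fold, 38.4-fold, 195-fold and 2.32-fold lower. The target gene Axin2 was 6.90-fold and Tcf7 4.84-fold higher. Of 5 measured Hedgehog genes 4 were at least 2-fold lower, with a median of -2.54 at percentile 0.010, which was -1.03 in cells taken by an Epcam or Cdh1 UMI, -1.22 with 5 CPM added and -1.38 with members from 1 CPM on. Gli3 was 8.84-fold, Gli2 16.3-fold, the ligand Shh 7.41-fold and its receptor Ptch1 2.19-fold lower.

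Notch and BMP or TGF-beta genes went both ways. Of 12 Notch genes 3 were at least 2-fold lower and 2 higher, with a median log2 ratio of -0.18 at percentile 21.8. Notch1 was 8.30-fold, Jag2 6.43-fold and Nrarp 5.79-fold lower, and Hes6 2.86-fold and Dtx4 2.97-fold higher. Of 16 BMP and TGF-beta genes 3 were at least 2-fold higher and 2 lower, with a median of -0.14 at percentile 20.3. This median was 0.21 when every cell weighed equally, and 0.47 at the highest. It kept its sign under 12 of 17 alternatives. Tgfb2 was 6.41-fold, Tgfb3 3.03-fold and Smad7 2.77-fold higher, Bmp7 was 4.48-fold lower and Tgfbi had 7.02 and 0.877 CPM. Retinoid genes had a median of -0.97, below those of all 10000 random lists, with 6 of 13 at least 2-fold lower and 3 higher. In cells taken by an Epcam or Cdh1 UMI the median was 0.11, and with members from 1 CPM on it was 0.12. Rarb was 5.56-fold and the retinoic acid hydroxylase Cyp26a1 52.9-fold lower. Aldh1a1 and Rdh10, enzymes that make retinoic acid and retinal, were 17.0-fold and 12.5-fold higher, and Rbp4 was 6.27-fold higher.

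Immediate-early genes, which respond within minutes to handling and other stimuli, were higher in p63-KO epithelial-like cells. The p63-KO library also had more barcodes over 10% mitochondrial UMIs, 9.32% against 2.20%, and a higher median mitochondrial share, 3.96% against 3.09% of UMIs over all barcodes. Of 17 genes 12 were at least 2-fold higher and 1 lower, with a median log2 ratio of 1.46, above those of all 10000 random lists. In cells with Y-linked RNA alone it was 2.25. Nr4a1 was 9.74-fold, Btg2 5.06-fold, Egr1 4.21-fold and Fos 4.17-fold higher, Jun had 395 and 712 CPM, Jund 535 and 1064 CPM, and the heat shock gene Hspa1a was 2.95-fold lower. Fos and Egr1 were also abundant in p63-KO fibroblast-like cells, with 1457 and 1287 CPM. The 10 wild-type fibroblast-like cells had 9 Fos UMIs, 184 CPM (84.3 to 350), and 8 Egr1 UMIs, 164 CPM (70.7 to 323).

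The remaining lists had medians closer to 0 or few measured members. The p53 targets had a median log2 ratio of -0.20 at percentile 19.7. Phlda3 was 4.31-fold lower, Cdkn1a had 247 and 128 CPM, Sesn1 134 and 78.9 CPM, and Fas 6.39 and 12.3 CPM. Hypoxia and glycolysis genes had a median of 0.17 at percentile 85.7, with 5 of 13 at least 2-fold higher, among them Egln3 3.25-fold, Pfkp 3.09-fold, Vegfa 2.78-fold and Bnip3 2.34-fold. Glutathione and NRF2 target genes had a median of 0.27 at percentile 85.5. Gsta3 was 5.93-fold and Slc7a11 7.66-fold higher, Gsta2 3.77-fold and Gsta1 4.16-fold lower, and Gsto1 had 3555 and 6019 CPM. Antigen presentation and interferon genes had a median of 0.38 at percentile 92.3, which was 1.14 with members from 20 CPM on, with H2-K1 4.30-fold, Psmb8 4.39-fold, Bst2 2.85-fold and Irf1 2.45-fold higher. Of 20 chemokine and cytokine genes 6 were measured, with a median of 2.06 at percentile 95.3, which was 1.27 with 5 CPM added. S100a8, with 0 wild-type UMIs, was at least 145-fold higher by the exact interval and 179-fold against 3 counts, S100a9 79.3-fold and Cxcl17 6.93-fold higher, and Il1rn was 6.70-fold lower. The S100a8 and S100a9 UMIs came from few cells, 0.238% and 0.536% of p63-KO epithelial-like cells.

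Within the wild-type library the epithelial-like cells formed 10 subclusters, named by the fixed markers and described here by their leading genes. Subcluster 7, basal-like, held 415 cells, 7.74% (7.04 to 8.49), led by Zbtb16, Tenm2, Ccbe1, Edaradd and Tnfrsf19. It had 1204 CPM of Krt5, 906 CPM of Krt14 and 502 CPM of Trp63. Subclusters 1, 4, 5 and 6 had 976 to 1147 CPM of Krt5, 422 to 471 CPM of Krt14 and 366 to 490 CPM of Trp63, so the name does not give the share of basal cells. Subclusters 3 and 8 were squamous suprabasal-like, with 649 and 395 cells, led by Serpinb3a, Spink5, Cyp4f39, Lipm and Dlg2 and by Ltf, Nccrp1, Ppbp, Crct1 and Cnfn. Subcluster 1, unnamed, was the largest with 1754 cells, 32.7%, led by Hs3st5, Mfap2, Nkain3, Kcnh1 and Shh. Subcluster 2, unnamed, held 667 cells led by Kcne3, Krtdap, 2610528A11Rik, Notch1 and Mctp1. Subclusters 4, 5 and 6, unnamed, were led by cell cycle genes such as Mybl2, Ube2c and Ccnb2. Subcluster 9, ciliated-like, held 26 cells, 0.485% (0.317 to 0.710), and subcluster 10, neuroendocrine-like, 2 cells.

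Within the p63-KO library there were 9 subclusters, and none met the naming rule for basal-like or squamous suprabasal-like cells. The rule compares a subcluster with the other p63-KO cells, so it does not show that squamous cells were absent. Subcluster 3, neuroendocrine-like, held 264 cells, 15.7% (14.0 to 17.6), led by Chgb, Car10, Asic2, Pcsk1n and Nrg3, and subcluster 7, also neuroendocrine-like, 85 cells led by Gzma, Cnpy1, Gsdma, Cbfa2t3 and Miat. Subcluster 5, mucous or club secretory-like, held 231 cells, 13.8%, led by Gm32647, Muc5b, Car12, Pdzrn4 and Slc7a11. It had 2439 CPM of Agr2 and 5543 CPM of Wfdc2. Subclusters 1, 2, 4, 8 and 9 had 508 to 728 CPM of Agr2 and 3678 to 5224 CPM of Wfdc2, so the name does not give the share of secretory cells. Subcluster 8, ciliated-like, held 60 cells, 3.57% (2.74 to 4.58), led by Ankfn1, Gm19935, Lrrc23, Dnah6 and Cfap299. Of these, 7 cells, 11.7% (4.82 to 22.6), held both Xist and Y-linked RNA, which a single cell should not have. Subcluster 6, unnamed, held 102 cells (6.08%) led by Tmprss11e, Trpm3, Atp6v0d2, Stap1 and March1, with 775 CPM of Foxi1, which was also counted in subcluster 9 at 189 CPM and in subcluster 7 at 60.5 CPM. Subclusters 1, 4 and 9, unnamed, were led by 2300002M23Rik and Asprv1, by Cryab and Ntf3, and by Slc4a9 and Dgki, and subcluster 9 had a median of 68538 UMIs. Krt13 was also among the leading genes of subcluster 1, at 4476 CPM, and Krt4 stood at 2215 CPM there. Subcluster 2, unnamed, held 285 cells led by Hist1h1b, Ube2c and other cell cycle genes, with a median of 68531 UMIs. Subcluster 6 also held cell cycle RNA, and Mki67 stood at 113 CPM in both subclusters 2 and 6. Subclusters were built within a library, and their sizes are not compared between libraries. At resolution 1 a squamous suprabasal-like class appeared in p63-KO, with 16.02% of cells.

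**Figure D4:**
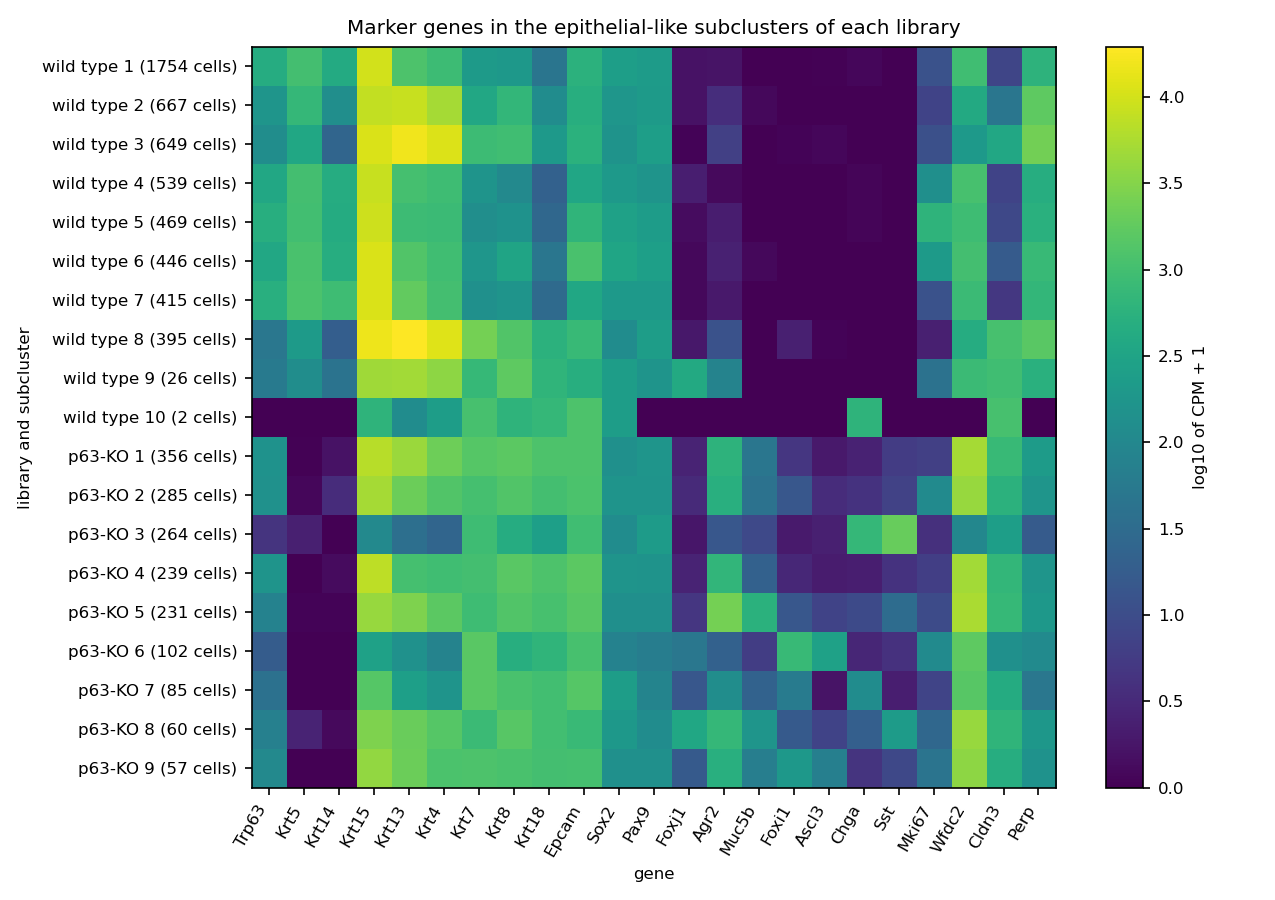
Colour shows log10 of CPM + 1 of marker genes (columns) in each epithelial-like subcluster (rows) of the wild-type and p63-KO library. Krt5 is at most 1.71 CPM in every p63-KO subcluster, and Foxi1 reaches 775 CPM in p63-KO subcluster 6.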

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

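The tests of the 3 patterns in this part were all chosen after the values were seen. Both signals listed first lie outside the comparisons of epithelial-like cells and exceeded the wild-type level. Barcodes over 10% mitochondrial UMIs, which were left out, were 263 of 2821 in the p63-KO library, 9.32% (8.27 to 10.5), against 2.20% (1.85 to 2.61) in the wild type. Endothelial-like cells were 2.91% (2.27 to 3.66) of kept p63-KO cells and 0.0181% of kept wild-type cells.

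The p63-KO library held 515 fibroblast-like cells and the wild-type library 10. Cells with Xist RNA were 97.2% (95.4 to 98.5) of 504 fibroblast-like p63-KO cells called by Xist or Y-linked RNA, against 64.1% (61.7 to 66.4) of 1626 epithelial-like ones, and 10 of 10 in the wild type. The other p63-KO classes had 64 of 64 endothelial-like, 17 of 17 immune-like and 61 of 67 smooth muscle or pericyte-like cells with Xist RNA. Yet 3 epithelial-like subclusters of at least 20 called cells lay more than 10 percentage points from their library with intervals that did not overlap, at 87.0% of 54 and 47.3% of 55 cells in p63-KO, and at 97.0% of 398 cells in the wild type against 71.9% of all epithelial-like ones, so uneven dissection between the pooled embryos and an effect of p63 loss cannot be told apart. An effect that differs with sex or embryo also remains open, since the number of embryos is not known.

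Trp63 RNA remained in p63-KO epithelial-like cells. Free RNA would reach other cells too, but 0 of 509 thinned p63-KO fibroblast-like cells held a Trp63 UMI, with an upper limit of 0.722%, against 17.1% of epithelial-like cells. Wild-type or heterozygous cells mixed into the library would bring Krt5 to about 299.6 CPM at the Trp63 level seen, and Krt5 was at 0.237 CPM. Both explanations are argued against as the whole cause. Transcripts of the targeted allele that keep the counted 3' end remain open and were not tested, since the files hold no read positions.

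Neuroendocrine-like cells and subcluster 6, which had the most Foxi1, 451 cells in all, stood out in p63-KO. Cells of a single embryo would hold nearly all or nearly no Xist cells. The share was 66.1%, against 63.3% of the other epithelial-like cells, which argues against that explanation. By subcluster the share was 68.5% in subcluster 3, 70.7% in subcluster 7 and 56.1% in subcluster 6. Airway or lung tissue remains open, since Nkx2-1 UMIs were found in 0 of these cells, with an upper limit of 0.815%, but in at most 0.506% of any class or subcluster of at least 20 cells, so how often expressing cells hold a UMI is not known. Glandular stomach or intestine also remains open, since Gata4, Cdx2 or Pdx1 UMIs were found in 0.443% (0.0538 to 1.59) of the cells, which decides neither way. For both tissues the subclusters were pooled, so these shares do not speak for each of them. An effect of the genotype is not separable from the library with 1 library per group.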

How the results depend on the processing

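Leaving out a library was not possible with 1 per group, and the comparison of fibroblast-like cells and the spread by compartment were not run. No paired analysis was possible because each group had 1 library. The subsets by cluster, Xist or Y-linked RNA, and the thinning before summing, were chosen after seeing the data. Median log2 ratios of the basal, hemidesmosome, desmosome, squamous, simple keratin and mucous lists kept their sign under all 17 alternatives, with ranges of -2.15 to -1.65, -1.22 to -0.54, -1.89 to -1.15, -2.77 to -1.83, 0.78 to 1.43 and 2.56 to 3.62. Those of the gastric, neuroendocrine, Wnt, Hedgehog, immediate-early, claudin and antigen lists also kept it, with ranges of 0.86 to 9.40, 3.09 to 6.10, -2.69 to -1.09, -2.64 to -1.03, 1.07 to 2.25, 0.20 to 0.61 and 0.26 to 1.14, and that of the chemokines under 16, with 1.27 to 2.64. The respiratory, foregut factor, Notch, BMP, p53, hypoxia, retinoid and glutathione medians took both signs, with ranges of -0.48 to 0.48, -0.01 to 0.24, -0.56 to 0.07, -0.18 to 0.47, -0.29 to 0.07, -0.07 to 0.38, -0.99 to 0.12 and -0.19 to 0.63. Scaling moved the median of all genes by little, to -0.04 with median-of-ratios and -0.05 without the 50 most abundant genes, from -0.02.

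The multiciliogenesis median was -0.28 without the rare clusters. The motile cilium median was 1.21 with the stricter filter, 1.81 with cells weighed equally, 0.72 with 5 CPM added, 0.66 without proliferating clusters, 0.78 without rare clusters, 0.76 in Y-linked cells and 1.76 after thinning. The mitosis median was -0.98 with the stricter filter, -1.44 with cells weighed equally, 2.03 without proliferating clusters, which removed nearly only wild-type cells (5362 to 3964, against 1679 to 1677), -0.83 in Xist cells, -2.04 in Y-linked cells and -1.37 after thinning. The DNA replication median ranged from -0.87 to 0.12 and kept its sign under 16 of 17 alternatives. For the rest of these values the cause was not tested.

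The Trp63 ratio was -1.30 with the stricter filter, -1.40 in cells with an Epcam or Cdh1 UMI, -1.77 with cells weighed equally, -1.14 without proliferating and -1.14 without rare clusters, -1.16 in Xist cells, -1.65 in Y-linked cells and -1.73 after thinning. The epithelial-like share was 98.0% (looser filter), 98.1% (stricter) and 96.6% (Epcam or Cdh1) in the wild type, and 62.6% (stricter) and 78.1% (Epcam or Cdh1) in p63-KO. The proliferating shares in wild type and p63-KO were 13.5% and 4.65% at 1000 UMIs, 33.9% and 37.1% unthinned, 30.5% and 18.2% with 1 gene, and 13.7% and 4.83% with 3 genes. Their order depended on whether the cells were thinned. At resolution 0.3 the secretory class held 7.03% of p63-KO cells, and the wild-type basal and squamous classes 6.64% and 13.3%. At resolution 1 the squamous classes held 16.02% in p63-KO and 13.4% in the wild type. The causes of these were not tested.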

Other observations

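The genes in this part were chosen after values were seen, except the 6 ionocyte genes below, which were picked from general knowledge before their values were read. Upk1b, a uroplakin, had 613 CPM in wild-type and 40.1 CPM in p63-KO epithelial-like cells, and Upk3a had 133 and 11.7 CPM, while Upk2 had 75.0 and 68.3 CPM. Msln (mesothelin) had 65.3 and 519 CPM and Vtcn1 24.7 and 157 CPM, both higher in p63-KO. In the wild type Msln was at 407 CPM in the squamous suprabasal-like subcluster 8 and at 1.79 CPM in subcluster 1.

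Peptide hormone genes marked the larger neuroendocrine-like p63-KO subcluster 3, where Sst had 1984 CPM, Calca 1953 CPM, Pyy 773 CPM and Cck 298 CPM. The smaller subcluster 7 had 1.31 CPM of Sst and 561 CPM of Calca. Sst was also counted in the ciliated-like subcluster 8, at 223 CPM, and in subcluster 5, at 31.3 CPM. Hnf4a had 5.38 CPM and Pax9 227 CPM in subcluster 3.

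The p63-KO subcluster 6 held 102 cells with 775 CPM of Foxi1, 282 CPM of Ascl3 and 761 CPM of Cftr, genes known from ionocytes, the chloride and proton transporting cells of airway and other epithelia. It also had 113 CPM of Mki67, a proliferation gene. Subcluster 9 had 189 CPM of Foxi1 and 69.0 CPM of Ascl3, and joint cluster 15, with Foxi1 and Ascl3 among its leading genes, held 185 p63-KO cells, so 102 is not a count of all cells with these genes. The hypothesis that these cells are ionocyte-like was tested on 6 further genes of ionocytes and proton pumps, of which 5 were measured. Their median log2 fold against the other p63-KO epithelial-like cells was 4.42, above those of all 10000 random lists, with Atp6v1b1 at 88.6 against 3.81 CPM and Bsnd at 88.6 against 2.54 CPM. These values go with ionocyte-like cells only as a hypothesis. Those of Foxi1, Ascl3, Cftr and the proton pump gene Atp6v0d2 in the subcluster had already been seen. The subcluster was picked by its Foxi1 RNA and compared with the cells it was clustered away from. Random lists also do not match genes that are expressed together, so the rank among them adds little.

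Cells with Xist RNA made up 97.0% (94.8 to 98.4) of the called cells in the wild-type basal-like subcluster 7, against 71.9% (70.5 to 73.1) of all wild-type epithelial-like cells. Lef1, among the leading genes of this subcluster against the other wild-type epithelial-like cells, was at 73.4 CPM there. In the squamous suprabasal-like subcluster 8 it was at 0.339 CPM. Subclusters 1, 4, 5 and 6, closer to subcluster 7 in Krt5 and Trp63, are not compared with it one by one. No explanation was tested. Cells with at least 5 Xist and at least 4 Y-linked UMIs, which a single cell should not have, were 39 of 1679 p63-KO and 40 of 5362 wild-type epithelial-like cells. They were 11 of 285 cells in p63-KO subcluster 2 and 1 of 57 in subcluster 9, the ones with the deepest cells, 13 of 231 in the mucous or club secretory-like subcluster 5, 7 of 60 cells in the p63-KO ciliated-like subcluster 8, 2 of 26 in the wild-type ciliated-like subcluster 9 and 0 of the 451 cells of p63-KO subclusters 3, 6 and 7. Those 451 cells had a median of 15534 UMIs, against 38924 in the other p63-KO epithelial-like cells. Cells with fewer UMIs reach the definition less easily, so the 0 does not show that doublets were absent. If all p63-KO epithelial-like cells were doublets drawn at random, 46.0% would pair a Xist with a Y-linked cell. Not every such pair need reach the definition. With Xist UMIs also required to reach at least 0.2 of the Y-linked UMIs, 32 p63-KO and 40 wild-type cells met the definition.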
